A study of Mus musculus with 3 samples.

How the data were processed

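DNase-seq libraries were prepared from MC3T3-E1 subclone 4 cultures at day 0, day 9 and day 28, with 2 biological repeats per day, each made of 2 technical repeats, per the labels and the series' design text. Nuclei were digested over a range of DNase I amounts, cut ends were joined to an adapter with an MmeI site, and MmeI released short tags for sequencing, per the labels' protocols. Reads of 36 bases came from a Genome Analyzer II and reads of 100 bases from a HiSeq, and which library used which instrument is not given in the sources used here. The labels list an early and a late passage for every sample without saying which repeat used which. CASAVA 1.6 for base calls, Bowtie 1.1.2 and the mouse build mm9 are named in the submitters' processing notes. The region caller, its threshold and the treatment of technical repeats are not given in the sources used here.

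The deposited lists hold 1 region per line with chromosome, start, end, a running name and the authors' score, in 5 columns without a header. Regions were called separately in each biological repeat, as the separate lists show. The day of each list was taken from the labels, and the repeat number from the numbering of the 2 deposited lists of that day. The lowest score differed between lists, from 0.0166 in repeat 2 of day 0 to 0.0330 in repeat 1 of day 28, so the deposited scores are on scales that were not compared between lists. Scores served only to rank and filter regions within a list. Read depth is unknown, which leaves open whether a region missing from a list was closed or was missed for want of reads. Intervals given for shares of regions are exact binomial unless named otherwise, and they cover counting error only.

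Regions of the 6 lists that overlapped by at least 1 bp were merged, and each merged region was scored as present or absent in each list. The lists held 8 regions of zero width, all in repeat 1 of day 28, and these were left out of overlaps. A region was called gained where both repeats of the later day and neither repeat of the earlier day held it, and lost in the reverse case. The count was set beside the other 2 ways of splitting the same 4 lists into pairs. Overlap between lists was the Jaccard index of bases (bedtools 2.31.1), tested by an exact permutation over the 15 ways of pairing 6 lists. The rule for named regions was fixed before the data were examined: the 5 widest gained and the 5 widest lost merged regions of each comparison. Gained and lost regions, the library overlap and their alternatives were fixed at the same time. Coordinates are 1-based in mm9.

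Several measures were chosen after the data were seen. Strong regions were those among the 50000 highest-scoring of both repeats of one day and absent from the full lists of the other day, and longer lists had been looked at before this number was settled on. The strong regions named by position were taken from those with the lowest sum of ranks. The odds ratio compares gain against loss in repeat 2 between regions gained and lost in repeat 1, with a 95% interval from leaving out each chromosome in turn. This interval covers the spread between chromosomes and not the spread between cultures. Chromosomes and 1 Mb windows with at least 10 changed regions were tested for their share of gains by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment within each comparison. The comparisons of chromosome X, of window density and of overlap between lists of unlike repeat number were also added then. Neighbouring strong regions within 50 kb were compared with 10000 random draws of the same number of strong regions. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

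Deviations of the repeats from the mean of their day correlated between days at 0.164 (days 0 and 9), 0.219 (days 9 and 28) and 0.137 (days 0 and 28) over merged regions, so lists with the same repeat number were treated as paired. A region gained or lost in both repeats is, by its construction, gained or lost within each of those pairs. The procedure was tested on simulated lists of 92658 sites with 200 gained and 200 lost sites planted between day 0 and day 9. It recovered 89.0% of the gains and 86.5% of the losses. Of 940 gained and 926 lost calls between those days, 178 and 173 were planted. Random drop-out of sites alone gave 735 gained and 714 lost calls between day 9 and day 28, where none had been planted. The drop-out rate was chosen for the simulation, independent and alike in all lists, so recovery and false calls follow from it. These figures check the counting and give no error rate for the real lists.

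The alternatives tried for gained and lost regions were an overlap of 50% of the shorter region, lists of equal length (213810 regions), the top 50% of each list by score, regions of at least 150 bp, presence in either repeat, each repeat alone, and chromosomes 1 to 19, X and Y only. The last was chosen after the data were seen. A test of signal between days was planned for counts, and the lists hold none, so it was not computed. Position relative to genes, gene lists and sequence motifs were also planned, but an annotation and genome sequence of mm9 were not used here, and no coordinates were converted, so these are not analysed here and regions are given by position alone.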

Results

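DNase I hypersensitive regions, stretches of chromatin that the nuclease DNase I reaches and cuts easily, were mapped in MC3T3-E1 subclone 4 cells, a preosteoblast line from mouse calvaria that deposits and then mineralizes a collagen matrix when given ascorbic acid and beta-glycerophosphate. Cultures were taken at day 0 (growth), day 9 (matrix deposition) and day 28 (mineralization), with 2 independent biological repeats per day and 1 list of regions per repeat, 6 lists in all. The 2 repeats of day 0 listed 333012 and 256184 regions that covered 113 and 106 Mb. At day 9 the lists held 213810 and 348904 regions over 70.6 and 114 Mb, and at day 28 they held 258538 and 326691 regions over 86.9 and 99.0 Mb. Repeat 1 had the longer list at day 0 and repeat 2 at days 9 and 28, so the number of regions did not follow the day. Median region width lay between 219 and 266 bp in the 6 lists. Each region carries the authors' score, which was used here only to rank regions inside one list. The read depth behind each list is unknown, so no counting interval can be given for any single region.

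Merging the 6 lists gave 771319 distinct regions in mm9 coordinates. A core of 71842 regions (9.31%) was present in all 6 lists, with a median merged width of 834 bp, against 137 bp for the 423917 regions (55.0%) seen in a single list. Merged width spans all lists that hold a region, so part of this difference is built in. The widest merged extents among them lay on chromosome 8 from 126060967 to 126148625 (87.7 kb), chromosome 11 from 3025112 to 3100180 (75.1 kb) and chromosome X from 166577472 to 166637311 (59.8 kb). These extents join regions by overlaps of at least 1 bp and were not listed whole in every list. The widest single region was 38576 bp in repeat 1 of day 9 and 87659 bp in repeat 2 of day 9. Among regions found in both lists of some days and in no list of the others, 15946 were present at day 0 alone, 2286 at day 9 alone and 2785 at day 28 alone. Another 3087 were shared by days 9 and 28 and absent at day 0, 2251 were shared by days 0 and 9, and 1290 by days 0 and 28. Sets that followed the repeat number held 14201 regions (repeat 1 of all days), 10629 (repeat 2 of all days), 4881 (repeat 1 of days 9 and 28) and 45781 (repeat 2 of days 9 and 28).

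The question of whether repeats of one day resemble each other more than they resemble other days was answered with the Jaccard index, the bases shared by a pair of lists divided by the bases in either. The repeats of day 0 overlapped at 0.456, those of day 9 at 0.349 and those of day 28 at 0.334, a mean of 0.380. Pairs of lists from different days averaged 0.389. The closest pair of all was repeat 1 of day 9 with repeat 1 of day 28 (0.493), and the most distant was repeat 1 of day 0 with repeat 2 of day 28 (0.292). Lists from different days with the same repeat number averaged 0.425, and those with different repeat numbers 0.354. Of the 15 ways to put the 6 lists into 3 pairs, 9 gave a within-pair mean at least as high as that of the days (one-sided exact permutation p = 0.6, with 0.0667 the smallest p this design allows). The repeats of a day never share a repeat number, and against lists of other days with a different repeat number the day mean was higher by 0.0262. Of the 6 ways to match the lists of repeat 1 to those of repeat 2, 2 gave a difference at least as high (one-sided exact permutation p = 0.333, smallest possible 0.167). Neither test separated the days, and the sign of the difference turned with the pairs compared.

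**Figure D1:**
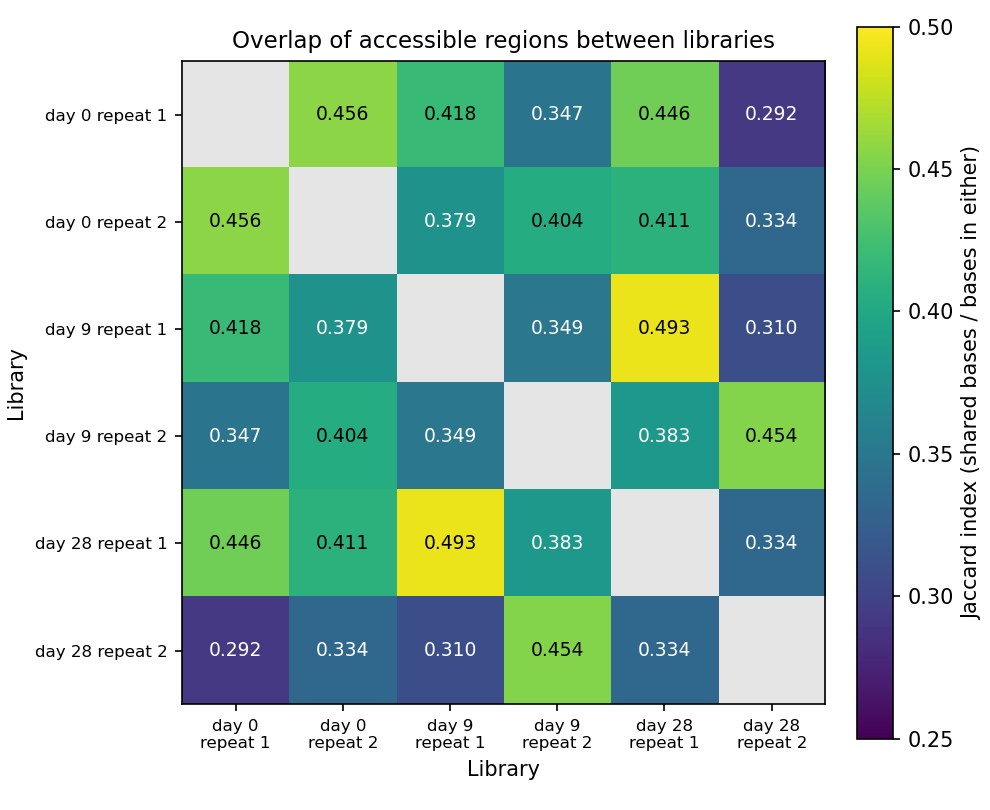
Jaccard index of bases for the 15 pairs of the 6 libraries (rows and columns, 2 biological repeats for each of 3 days); the diagonal is left grey. The brightest cell joins repeat 1 of days 9 and 28 (0.493), and the repeats of day 28 overlap at 0.334.

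Between growth and matrix deposition, 8858 regions were gained, meaning present in both repeats at day 9 and in neither at day 0, and 24951 were lost. The widest gained region lay on chromosome 9 from 61011297 to 61013243, and both day 28 lists also held it. The next widest were on chromosome 6 from 23408779 to 23410666, chromosome 12 from 74582229 to 74583805, chromosome 6 from 93326207 to 93327743 and chromosome 8 from 109433136 to 109434659. By score these 5 gains ranked from 49613 to 205040 of 213810 in repeat 1 of day 9. In repeat 2 of day 9 they ranked from 67837 to 141037 of 348904. The widest lost region, on chromosome 5 from 124938560 to 124940556, ranked 48006 and 54041 by score in the day 0 lists and was absent from all 4 later lists. Losses of similar width occurred on chromosome 9 from 99031294 to 99033119, chromosome 5 from 102063649 to 102065299, chromosome 2 from 135324732 to 135326358 and chromosome 6 from 34477406 to 34478976. The 5 losses ranked from 37450 to 235581 of 333012 in repeat 1 of day 0. In repeat 2 of day 0 they ranked from 22910 to 137494 of 256184. The region on chromosome 5 from 102063649 returned in both day 28 lists. Pairing the same 4 lists by repeat number instead separated 53430 regions and the crossed pairing 21773, against 33809 for the days, and 3 pairings cannot give a p under 0.05. Each repeat alone had an opposite balance: repeat 1 gained 60686 and lost 179215 regions, and repeat 2 gained 188213 and lost 101452. With presence in either repeat counted, gains (200068) slightly outnumbered losses (196625).

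Strong regions were taken as those among the 50000 highest-scoring of both repeats of one day and absent from the full lists of both repeats of the other day, a definition chosen after the data were seen. From day 0 to day 9, 179 strong regions were gained and 175 were lost. The pairing by repeat number gave 273 such regions and the crossed pairing 1. The counts moved with the number of regions taken: 15 gained and 2 lost among the 25000 highest-scoring, 1149 gained and 2286 lost among the 100000 highest-scoring. Among the strong gains with the best summed rank were regions on chromosome 4 from 62388378 to 62389221 (ranks 7623 and 9363 in the day 9 lists), chromosome 9 from 113951280 to 113952256 (14969 and 11452), chromosome 8 from 95142039 to 95142643 (14774 and 13061) and chromosome 10 from 116531418 to 116532567 (11156 and 20584). The strongest losses included chromosome 2 from 152151807 to 152153096 (ranks 12781 and 19493 in the day 0 lists), chromosome 6 from 142315830 to 142316922 (23103 and 13080) and chromosome 15 from 11724152 to 11725162 (27247 and 13716). These strong changed regions had a median merged width of 671 bp in both directions, against 1129 bp for other strong day 9 regions and 1075 bp for other strong day 0 regions. Changed regions are by definition absent from both lists of a day, and merging over fewer lists gives narrower regions, so part of this difference is built in. Among regions that changed in each repeat, 60.8% changed in the same direction in both, and the odds of a gain in repeat 2 were 3.40 times higher where repeat 1 gained the region than where it lost it (95% confidence interval 2.98 to 3.88, jackknife over chromosomes).

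**Figure D2:**
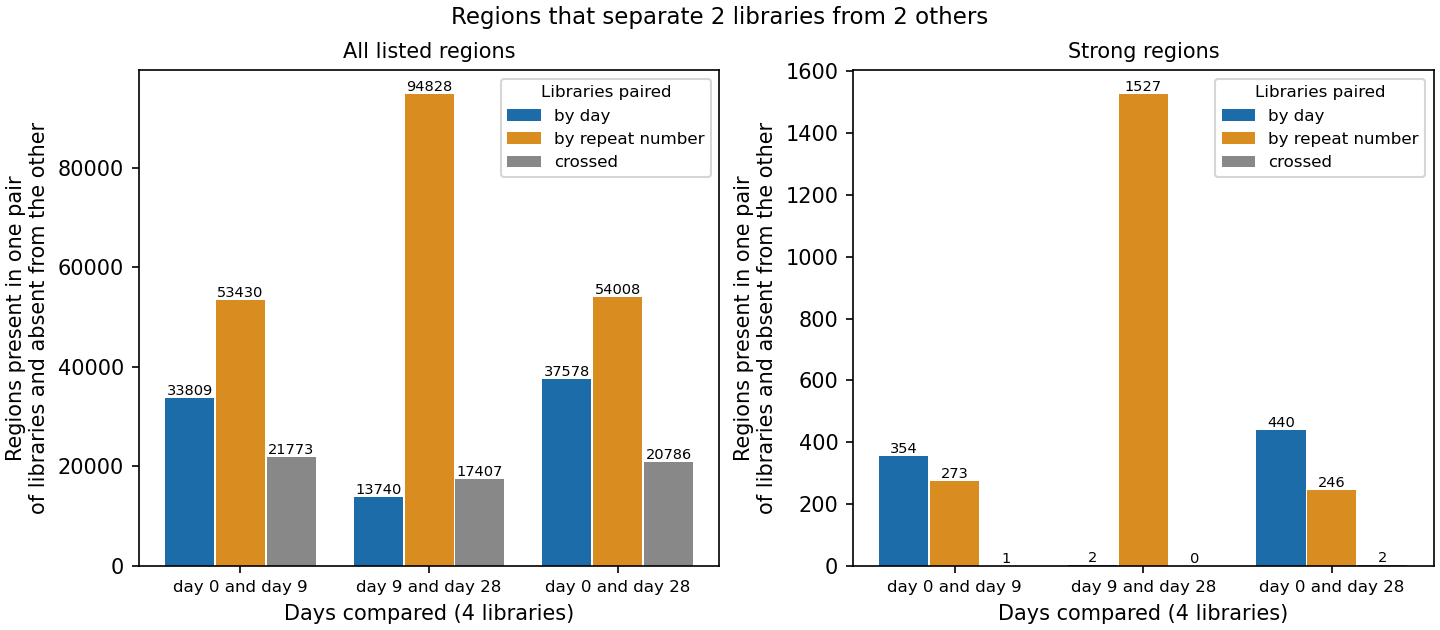
Number of regions (vertical axes) present in one pair of libraries and absent from the other pair, for each choice of 2 days (horizontal axes) and each way of pairing the 4 libraries; left, all regions, right, strong regions. Pairing by repeat number separates the most regions in the left panel, while among strong regions pairing by day gives 354 and 440 where day 0 is compared and 2 where days 9 and 28 are compared.

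Strong regions that changed by day 9 were then looked up in the mineralizing cultures of day 28. Of the 179 strong regions gained by day 9, 178 (99.4%) were in both day 28 lists, as were 99.9% of the 33917 other strong day 9 regions. Of the 175 strong regions lost by day 9, 71 (40.6%) were in neither day 28 list, 98 were in 1 and 6 were in both. Of 39496 other strong day 0 regions, 137 (0.347%) were absent from both day 28 lists. These were not a matched set: the losses had been chosen for absence from both day 9 lists. The losses were also narrower (median merged width 671 against 1075 bp). Regions at the edge of detection would differ in the same way, so the contrast does not show lasting loss. Presence and rank in the day 28 lists were not used to choose these regions, although those lists were among the 6 that were merged and so shaped the regions' extents. Across all ranks, 3087 of 8858 gained regions (34.8%) were in both day 28 lists and 15946 of 24951 lost regions (63.9%) were in neither, a lower share than among strong gains and a higher share than among strong losses.

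**Figure D3:**
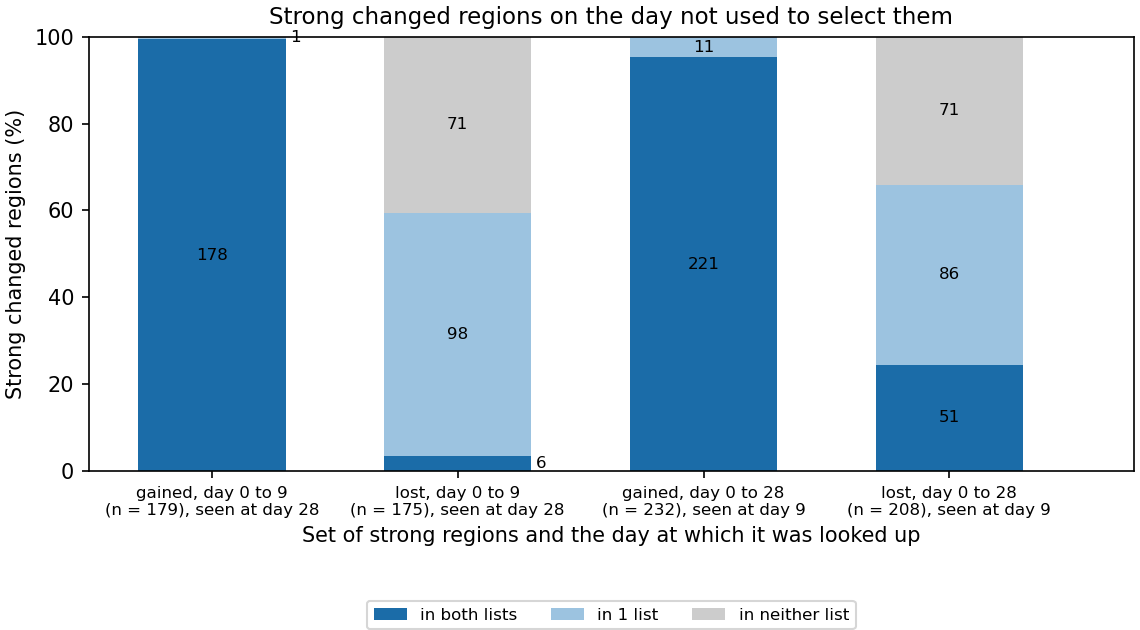
Share in percent (vertical axis) of strong changed regions found in both lists, in 1 list or in neither list of the remaining day. Presence and rank on that day were not used to select them. Counts are on the bars. Regions gained from day 0 to day 9 were in both day 28 lists in 178 of 179 cases, and regions lost over the same interval were in neither list in 71 of 175.

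Between matrix deposition and mineralization, 6295 regions were gained and 7445 were lost, together 13740, while the other pairings of the same 4 lists separated 94828 (by repeat number) and 17407 (crossed). With presence in either repeat counted the balance turned to 196447 gained and 173585 lost. Only 2 strong regions were gained and 0 were lost, against 1527 for the pairing by repeat number. The strong gains, named after their values were seen, lay on chromosome 16 from 25805010 to 25805468 and on chromosome 8 from 71499654 to 71500071. The widest gained regions of any rank were on chromosome 2 from 90462055 to 90464067, chromosome 15 from 8468244 to 8470098, chromosome 5 from 102063649 to 102065299, chromosome 18 from 15272169 to 15273692 and chromosome 2 from 179580633 to 179582000, and at least 1 day 0 list held each of them. The widest lost regions, all of them also present in both day 0 lists, were on chromosome 5 from 30920094 to 30922106, chromosome 6 from 118285885 to 118287671, chromosome 10 from 122213849 to 122215606, chromosome 4 from 114267762 to 114269483 and chromosome 8 from 24591929 to 24593541. At day 28 the widest gains ranked from 128247 to 219184 of 258538 in repeat 1. In repeat 2 those gains ranked from 52271 to 230776 of 326691. At day 9 the widest losses ranked from 81688 to 183091 of 213810 in repeat 1. In repeat 2 those losses ranked from 107108 to 337735 of 348904. In repeat 1 alone 114169 regions were gained and 69928 lost, and in repeat 2 alone 131336 were gained and 153458 lost. The repeats changed in the same direction at 44.1% of the regions that changed in each, with an odds ratio of 1.06 (95% confidence interval 0.989 to 1.13). With all regions this interval included 1, although it lay above 1 under 3 stricter settings. It covers the spread between chromosomes only. Whether a change from day 9 to day 28 was common to both repeats cannot be told from differences between cultures by it.

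From growth to mineralization, 10844 regions were gained and 26734 were lost, together 37578. The other pairings of the same 4 lists separated 54008 (by repeat number) and 20786 (crossed). Repeat 1 alone gained 85385 and lost 159673 regions, and repeat 2 alone gained 189567 and lost 124928. The widest gains were on chromosome 14 from 60610805 to 60614245, chromosome 4 from 61346789 to 61349592, chromosome 15 from 91821223 to 91823579, chromosome 7 from 48428810 to 48430867 and chromosome 9 from 61011297 to 61013243. The last of these was also the widest gain at day 9. The others were each in the day 9 list of repeat 2 and absent from that of repeat 1. In repeat 1 of day 28 those others ranked from 120221 to 253912 of 258538 regions. The widest losses were on chromosome 6 from 82999032 to 83001109, chromosome 8 from 28344133 to 28346149, chromosome 5 from 30920094 to 30922106, chromosome 5 from 124938560 to 124940556 and chromosome 16 from 96370158 to 96372063. With presence in either repeat counted, 224458 were gained and 198153 lost. Strong regions numbered 232 gained and 208 lost, against 246 for the pairing by repeat number and 2 for the crossed pairing. Of the strong gains, 221 (95.3%) were in both day 9 lists and the other 11 were in 1. Of the 32658 other strong day 28 regions, 99.7% were in both day 9 lists. The measure is thus near its ceiling and does not tell when the gains arose. Of the strong losses, 71 (34.1%) were absent from both day 9 lists, 86 were in 1 and 51 were in both. These 71 are the same regions as the 71 strong losses of day 9 absent at day 28, so they are not a second result. By comparison, 104 of 39463 other strong day 0 regions (0.264%) were absent from both day 9 lists. The repeats changed in the same direction at 64.4% of the regions that changed in each, with an odds ratio of 2.92 (95% confidence interval 2.73 to 3.13). The 2 comparisons with day 0 use the same day 0 lists, so their counts are not independent.

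The balance of gains and losses differed between chromosomes. From day 0 to day 9, gains made up 26.2% of all changed regions, but 17.1% on chromosome 19 and 20.1% on chromosome 11, and 36.5% on chromosome 18 and 36.8% on chromosome X. From day 0 to day 28 the share was 28.9% over the genome, 19.4% on chromosome 19, 19.7% on chromosome 6 and 47.5% on chromosome X. Each of these 7 chromosome values differed from the rest of the genome by Fisher's exact test with Benjamini-Hochberg adjustment over 20 chromosomes (adjusted p from 3.19e-30 to 1.46e-07). In each repeat alone the chromosome lay on the same side of the genome's share. Regions changed in both repeats are counted in each repeat alone, so this agreement, here and below, is partly built in. Other chromosomes passed with their repeats on different sides: chromosomes 5, 6 and 8 from day 0 to day 9, and chromosome 7 from day 0 to day 28. The size of the departure differed between repeats: from day 0 to day 9 chromosome X stood at 26.9% against 25.3% over the genome in repeat 1 and at 86.5% against 65.0% in repeat 2. Likewise, chromosome 6 from day 0 to day 28 stood at 32.6% against 34.8% in repeat 1 and at 45.8% against 60.3% in repeat 2, where it held 9.05% of the day 0 list (6.31% in repeat 1). From day 9 to day 28 chromosome 6 stood out with 364 gained and 691 lost regions (34.5% gained against 45.8% over the genome, Fisher's exact test, adjusted p = 1.91e-13), again in both repeats. Chromosome 5 passed in the other direction with 476 gained and 446 lost (exact test, adjusted p = 0.00283), but its repeats lay on different sides of the genome's share. These tests take regions as units, so the p-values describe the lists and not the spread between cultures. Strong regions were few on each chromosome: from day 0 to day 9 chromosome 19 had 5 gained and 7 lost, chromosome 11 had 13 and 14, chromosome 18 had 9 and 3, and chromosome X had 1 and 1. From day 0 to day 28, chromosome 19 had 5 strong gains and 9 strong losses, chromosome 6 had 17 and 12, and chromosome X had 0 and 2, beside 232 and 208 over the genome. The strong counts per chromosome were not tested.

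**Figure D4:**
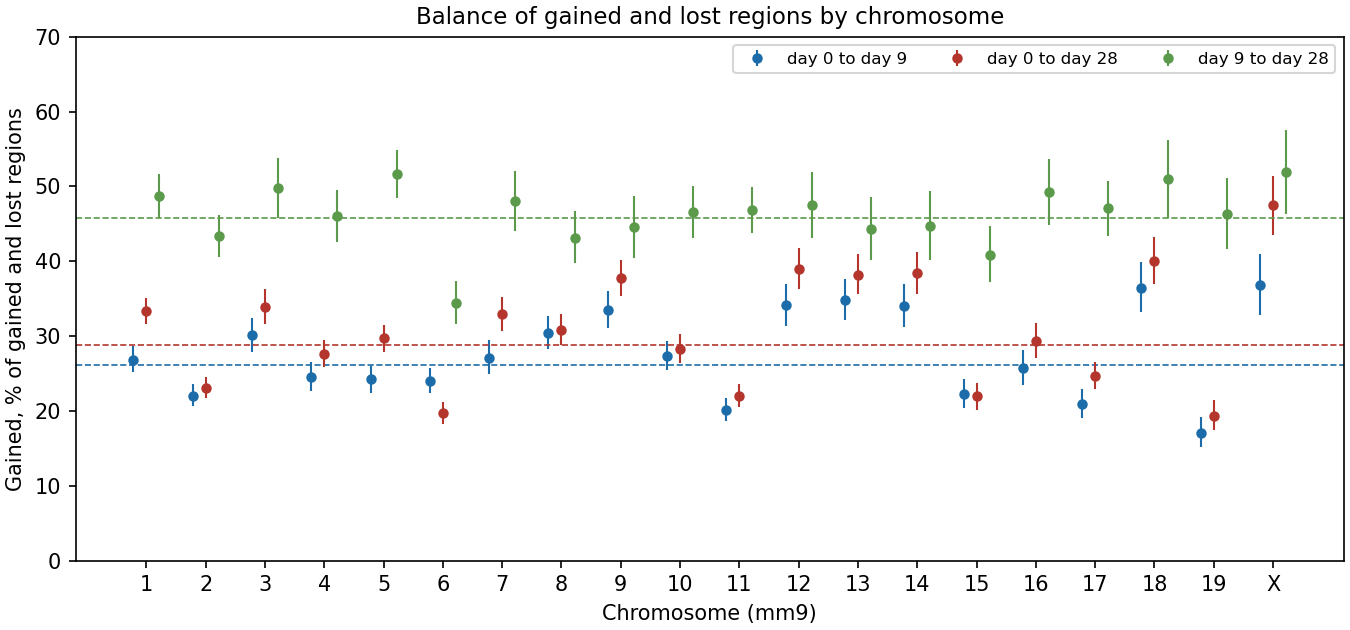
Gained regions as a percentage of gained and lost regions (vertical axis) on chromosomes 1 to 19 and X (horizontal axis) for 3 comparisons; points are values over both repeats, bars are 95% Wilson intervals and dashed lines are the genome's values. Chromosome 19 lies lowest from day 0 to day 9 (17.1%), chromosome X highest from day 0 to day 28 among the comparisons with day 0 (47.5%), and chromosome 6 lowest from day 9 to day 28 (34.5%).

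Windows of 1 Mb with at least 10 changed regions were tested in the same way. Some of those named below lie on chromosomes that departed as a whole in the same direction, such as chromosome 19. Others do not: chromosome 10 from day 0 to day 9 was 27.4% gained (Fisher's exact test, adjusted p = 0.273). From day 0 to day 9, 58 of 1358 windows departed from the genome's balance at an adjusted p of 0.05, 37 toward gains and 21 toward losses. Both repeats alone showed the direction in 29 and 21 of them. Regions changed in both repeats enter the count of each repeat alone, so this agreement, here and from day 0 to day 28, is partly built in. On chromosome 8 from 117000001 to 118000000, 23 regions were gained and 7 lost (Fisher's exact test, adjusted p = 7.54e-06), and the adjoining window up to 119000000 had 19 gained and 7 lost. In repeat 1 alone losses outnumbered gains in both windows (52 gained and 66 lost, 41 gained and 52 lost). In repeat 2 alone gains outnumbered losses (138 and 54, 113 and 44). On chromosome 10 from 80000001 to 81000000, 0 regions were gained and 69 lost (exact test, adjusted p = 1.46e-06), and chromosome 19 from 6000001 to 7000000 had 0 gained and 48 lost. In each repeat alone losses outnumbered gains in these windows of losses. From day 0 to day 28, 29 of 1408 windows departed toward gains and 38 toward losses, and both repeats alone showed the direction in 23 and 38 of them. The lowest p again belonged to chromosome 10 from 80000001 to 81000000, with 2 gained and 69 lost (exact test, adjusted p = 2.87e-05), and among windows of gains to chromosome 5 from 132000001 to 133000000, with 15 gained and 1 lost (exact test, adjusted p = 4.36e-05). That window of gains had 66 gained and 79 lost in repeat 1 alone, and 82 gained and 7 lost in repeat 2 alone. From day 9 to day 28, 1 of 403 windows passed, on chromosome 6 from 126000001 to 127000000 with 0 gained and 15 lost (exact test, adjusted p = 0.0441). Shuffling gains and losses among the changed regions gave 0 such windows from day 0 to day 9, 1 from day 0 to day 28 and 0 from day 9 to day 28. Such shuffling treats regions as independent, so it checks the calling and does not show that the windows are local changes. Gains were a smaller part of the changes where regions in all 6 lists were dense: from day 0 to day 9 they made up 42.8% in the sparsest 25% of windows and 21.0% in the densest 25%. Among strong regions the same windows held 2 gained and 6 lost, and 93 gained and 92 lost.

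Chromosome X held a growing share of the list in repeat 2. The share was 1.52% of regions at day 0, 3.06% at day 9 and 3.70% at day 28 in repeat 2, and 1.72%, 1.87% and 2.03% in repeat 1. Later days relative to day 0 thus stood at 2.23 times in repeat 2 and 1.13 times in repeat 1. Among the 50000 highest-scoring regions the ratio in repeat 2 was 1.31 (95% confidence interval 1.20 to 1.43). The intervals cover counting error of regions only, and with 1 list per repeat and day the difference between repeats has no replicate check.

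**Figure D5:**
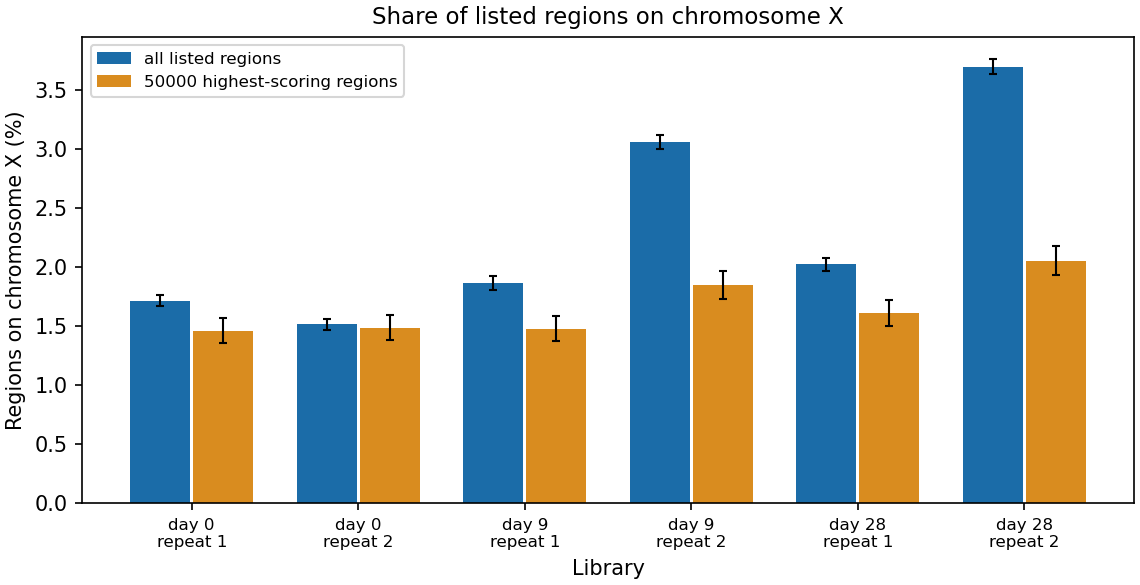
Share of listed regions on chromosome X in percent (vertical axis) in each of the 6 libraries (horizontal axis), over all regions and over the 50000 highest-scoring; error bars are 95% binomial intervals. In repeat 2 the share over all regions goes from 1.52% at day 0 to 3.70% at day 28.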

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

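The tests of this part were chosen after the result was seen, although lists of equal length had been planned as a setting. Regions on contigs outside chromosomes 1 to 19, X, Y and M, which cannot be gained or lost in both repeats, appeared in the 3 lists of repeat 1: 8554 at day 0, 4204 at day 9 and 7685 at day 28. They drew attention because the 3 lists of repeat 2 held 0 of them, and with no control sample a count above 3 was taken as a signal. Most lay on the unplaced part of chromosome Y, with 6974, 2958 and 6274 regions. The mitochondrial chromosome showed the opposite split, with 1 region in each list of repeat 1 and 6, 17 and 12 in repeat 2 at days 0, 9 and 28.

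The lists of the repeats thus differ in which sequences they cover. The pattern to weigh is that repeat number separated more regions than day between day 9 and day 28. The ratio of the repeat split to the day split was 6.90. Without the contigs it was 6.75, so the contigs do not account for it. With lists of equal length it was 6.99, which argues against list length. Passage and sequencing instrument cannot be told apart from the repeat number, because no label assigns either to a repeat. Shares of chromosomes among the 50000 highest-scoring regions also followed the repeat number on chromosomes 3 and 6, named after their values were seen. Chromosome 3 held 5.41%, 5.48% and 5.38% at days 0, 9 and 28 in repeat 1, and 4.55%, 4.32% and 4.32% in repeat 2. Chromosome 6 held 5.78%, 6.03% and 5.81% on those days in repeat 1, and 6.66%, 6.61% and 6.48% in repeat 2. Neither these shares nor the ratio of 6.90 can tell passage from instrument.

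A further pattern is that losses outnumbered gains after day 0. With lists of equal length the ratio of lost to gained from day 0 to day 9 was 2.27, which argues against list length as the whole cause. The balance shifted toward losses as weaker regions were taken in: 15 regions were gained and 2 lost among the 25000 highest-scoring, the ratio of lost to gained was 0.978 among the 50000 highest-scoring, and it was 1.99 (95% confidence interval 1.85 to 2.14) among the 100000 highest-scoring. The bound on the 100000 was added after the ratio at 50000, which alone would have met the prediction of weak regions as the cause, had been seen. In the top 50% of each list 13794 regions were lost and 4826 gained, but cutting the lists moves the threshold and cannot exclude its effect. The median lost region lay at percentile 44.4 of its list by score and the median gained region at 44.8, so this position did not set losses apart. The ratio among the 100000 highest-scoring, which were absent from the full lists of the other day, argues against regions at the very end of the lists that hold them as the whole cause. It does not address regions just below the threshold of the lists that lack them. List lengths were not made equal for this ratio. The excess nevertheless lies outside the highest ranks. A change of accessible chromatin on leaving growth stays open and untested, and the excess was not seen when presence in either repeat was counted (200068 gained and 196625 lost).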

How the results depend on the processing

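The settings for strong regions, for the odds ratio and for chromosomes 1 to 19, X and Y were chosen after the data were seen. Gained and lost counts stayed within 1.5 times of the reported values under 50% overlap and lists of equal length, in all 3 comparisons. Chromosomes 1 to 19, X and Y gave the same counts. This setting is no test of them, because contig regions were listed in repeat 1 only and cannot be gained or lost in both repeats. The top 50% of each list gave 4826 gained and 13794 lost from day 0 to day 9, 2307 and 2876 from day 9 to day 28, and 5762 and 14424 from day 0 to day 28. Shorter lists hold fewer regions by construction. Regions of at least 150 bp moved only the counts from day 9 to day 28, to 3823 gained and 4775 lost. Presence in either repeat gave 200068 gained and 196625 lost, 196447 and 173585, and 224458 and 198153 in the same order, so that losses no longer outnumbered gains in any comparison. Each repeat alone gave from day 0 to day 9 between 63765 and 191197 gained and between 105206 and 187762 lost regions. From day 9 to day 28 it gave 119124 to 133114 gained and 73162 to 156303 lost, and from day 0 to day 28 90043 to 191892 gained and 129090 to 168078 lost. These counts come from merging only the lists kept and rest on 1 list per day.

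Strong regions moved by less than 1.5 times under 50% overlap. Their counts were unchanged on chromosomes 1 to 19, X and Y, which is no test of them for the same reason. With the 25000 highest-scoring regions, 15 were gained and 2 lost from day 0 to day 9, 0 were gained and 0 lost from day 9 to day 28, and 20 were gained and 3 lost from day 0 to day 28. With 100000 the counts were 1149 and 2286, 71 and 100, and 1186 and 2510. In each repeat alone strong gains ranged from 1302 to 2698, 255 to 474 and 1526 to 4554, and strong losses from 1286 to 1862, 143 to 597 and 724 to 4595. The odds ratio kept its side of 1 under 5 settings in both comparisons with day 0, of which chromosomes 1 to 19, X and Y left it unchanged and is no test. From day 9 to day 28 its interval came to exclude 1 under 50% overlap (1.08), the top 50% of each list (1.19) and regions of at least 150 bp (1.12), and included it under the other 2; the cause was not tested. Similarity within days stayed below that between days under 4 settings. With the repeat number as a block, comparing only lists of unlike repeat number, the difference turned from -0.00948 to 0.0262 (exact permutation p = 0.333), because the pairs that share a repeat number leave the between-day mean. Gains and losses common to both repeats are by construction already counted within pairs. The depth of each list is unknown, which limits every statement on absence.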

Other observations

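In this part the test of window density was chosen after the result was seen, and strong regions were defined after the data were seen. The strong regions that changed between growth and matrix deposition were scattered along the genome. Of the 179 strong gains, 1.12% had another strong gain within 50 kb, inside the central 95% of random draws from strong day 9 regions (0 to 4.47%). The closest pair lay on chromosome 3 from 37719750 to 37738278. Of the 175 strong losses, 2.29% had such a neighbour (random range 0 to 4.57%), in pairs on chromosome 1 from 33774382 to 33782313 and from 137571867 to 137612241. Clusters of strong changes were thus no more frequent than among strong regions in general, in these lists and at this distance.

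Gains and losses of day 9 were looked up at day 28, as a test of whether each state lasted. Strong gains were still present in both day 28 lists in 99.4% of cases, as were 99.9% of other strong day 9 regions. With nearly every strong region present, the measure is at its ceiling, and neither lasting gain nor a difference in persistence can be read from it. Strong losses were absent from both day 28 lists in 40.6% of cases, short of the 50% set in advance for lasting loss and above the 20% set for return. Whether the regions listed in 1 repeat reopened or were listed at the edge of detection cannot be told apart without read depth.

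The share of regions on chromosome X in repeat 2 rose 2.23 times after day 0. Weak regions entering the list may account for part of the rise, since the ratio was 1.31 among the 50000 highest-scoring regions, between the bounds of 1.2 and 1.5 set before the test. Copies of the chromosome cannot be judged from these lists, because scores of different lists are not on one scale, and no biological explanation was tested.

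Gains were a larger share of the changed regions in windows with few constant regions than in dense ones, although dense windows held more gains (3785 in the densest 25% against 617 in the sparsest). From day 0 to day 9 the gained share ran from 42.8% in the sparsest 25% of 1 Mb windows through 33.3% and 30.0% to 21.0% in the densest 25%. In repeat 2 alone it was 88.8%, 75.5%, 64.3% and 52.6%, and in repeat 1 alone it was 29.5%, 30.8%, 27.6% and 21.9% from the sparsest to the densest, without a steady fall. Among strong regions the share in the densest windows (50.3%) exceeded that in the sparsest by 25.3 percentage points, the opposite direction, but the sparsest held 8 regions and the difference was not significant (Fisher's exact test, p = 0.279). Whether density sets the contrasts between chromosomes cannot be told apart from the listing of weak regions.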
